A study of Mus musculus with 6 samples.

How the data were processed

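RNA of peritoneal macrophages was extracted, enriched for poly-A mRNA and made into TruSeq libraries, per the labels' protocols, and sequenced on a HiSeq2000, per the series' design text. The authors deposited 1 table per library, with an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) and the lower and upper bound of its interval for each gene, per the file headers. Reads were converted with bcl2fastq 1.8.4, and TopHat, Cufflinks and the mouse build mm9 were used, per the submitters' processing notes. The versions of TopHat and Cufflinks, the annotation and any filter are not given in the sources used here. Neither is whether the triplicates named in the design text were pooled.

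Each table had 23699 rows for the same genes. Rows not marked OK in at least 1 library (349), 712 rows of 248 symbols listed at more than 1 locus and 786 rows of small RNA genes, which poly-A libraries of fragmented mRNA do not measure, were left out. This left 22178 rows. Of 10780 rows with at least 2 FPKM in a library, 201 were left out. FPKM summed to 573914, 681618 and 671951 in WT naive, LPS and tolerized cells and to 635180, 604885 and 639892 in the KO cells. Read counts were not used here. The widths of the deposited intervals, taken as 2 standard errors of a count, implied 21.2, 19.3, 24.7, 17.6, 21.9 and 25.0 M fragments in the same order, an estimate: 68.8% to 69.7% of values below 200 fragments came out whole within 0.01. The intervals had a median half-width of 13.7% to 16.1% at 2 to 5 FPKM and 5.0% to 6.0% from 10 FPKM, and cover counting error only. The 50 most abundant rows took 35.2%, 46.7% and 46.3% of FPKM in WT naive, LPS and tolerized cells and 38.8%, 43.8% and 42.7% in KO cells.

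Samples were grouped by their titles into 6 groups of 1 library. Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate those of low genes. With 1 library per group, the 9 comparisons of library pairs used a rule of size, at least 2-fold among genes with 2 FPKM or more in either library. Conditions and genotypes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided) on genotype plus condition without interaction, over 10139 genes with at least 2 FPKM in at least 2 libraries. That fit had 2 residual and 4.2 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. In it, each condition has 2 libraries and each genotype 3, and an effect in 1 genotype only counts as spread. The p-values measure the spread between these samples, and whether the libraries came from separate animals or cultures is not stated. The verbs rose and fell are used only of genes past that threshold or of list members past it over the list alone.

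Medians of 47 gene lists were set against 10000 random lists of the same size matched on mean expression in 20 bins, and stand apart outside the 2.5 to 97.5 percentile range. Of 423 such pairs of list and comparison 215 were outside, against 21 by chance, so most lists differ in some comparison. This describes these libraries and is not a test across replicates. Members of a list were adjusted over all genes and over the list alone. Rescaling divided each library by its median ratio to the common profile (median of ratios), with factors of 1.21, 0.82 and 1.09 in WT and 1.21, 0.74 and 1.06 in KO naive, LPS and tolerized cells. Because FPKM of other genes can fall when a few genes take a larger share, the all-gene median is given where it lay more than 0.1 from 0. The source of these shifts was not tested. The share of the 50 most abundant rows was higher with LPS than in naive cells of both genotypes. From LPS to tolerized cells it was 46.7% and 46.3% in WT and 43.8% and 42.7% in KO, while the all-gene medians were 0.47 and 0.56. For seed sites, 3′ UTR sequences were taken by symbol from the GRCm38 annotation, a later build than mm9, and no coordinates were moved between builds.

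The design, the tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each comparison of conditions, the 10 largest increases and 10 largest decreases averaged over WT and KO among genes with at least 10 FPKM in a library, past the threshold and of like direction in both genotypes. Between genotypes it took the 10 largest of each direction with the same direction in all 3 conditions, and for the difference of tolerization the 10 largest of each sign. It added 2 to 4 members with the largest value of each list described, and always Smarca4, Mir221, Mir222, Tnf, Il6, Il12b, Nos2, Stat2 and Irf9. A few genes that the rule selects are not reported here. Other genes are said to be named after their values were seen.

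The fit was tested on simulated data over 10139 genes with 200 changed. For LPS against naive it recovered 48% of genes changed by a log2 of 1 and 99% of those changed by 2, with 18 other genes called. For KO against WT it recovered 69% and 100%, with 14 others. The simulation drew independent normal noise without condition effects, and the planted changes themselves ease the adjustment. These shares therefore do not give what the real fit would recover. In the real limma fit of KO against WT, Ctla2a at -2.50 ± 0.20 had an adjusted p of 0.11. For tolerized KO against WT, over 9695 genes, 4.5% and 6.5% of unchanged lists of 10 and 20 genes lay outside the range, and 100% of lists raised by 0.5. For the seed test, a rise of 0.2 reached percentile 100 in naive (9889 genes, 1086 with a site), LPS (8408 and 896) and tolerized cells (9409 and 1034), and 10.0%, 0.0% and 0.0% of random sets lay outside. Alternatives were a pseudocount of 0.1, no filter and a filter of 5 FPKM, rescaled libraries, deposited intervals that do not overlap, each library left out, genes tolerized in 1 genotype alone and ATGTAGCA sites alone. Keeping the small RNA rows and repeated symbols was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.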

Results

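Gene expression was measured by sequencing poly-A mRNA of peritoneal macrophages, the phagocytes that reside in the abdominal cavity, from C57Bl/6 mice that were wild type (WT) or carried a knockout of the microRNA genes miR-221 and miR-222 (KO). Cells of each genotype were left untreated (naive), were given 1000 ng/ml lipopolysaccharide (LPS) for 4 h, or were tolerized. Tolerized cells received 10 ng/ml LPS for 15 h, were washed and rested for 2 h, and were then given 1000 ng/ml LPS for 4 h. LPS is a cell wall component of Gram-negative bacteria that signals through Toll-like receptor 4, and tolerance is the weaker response of cells that have met it before. Each of the 6 groups was 1 library, although the series describes triplicates, so differences between single libraries had no replicate check. The intervals in the deposited tables implied about 17.6 M to 25.0 M fragments per library, an estimate, and spanned 5.0% to 6.0% on either side of the value at 10 FPKM or more. The series is titled for the regulation of the tolerized response by miR-222. The design therefore asks what LPS changed, what earlier LPS changed in that response, and whether either differed in the knockout.

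The targeted genes were listed at 0 FPKM in all 6 libraries, Mir221 at X 18723420 to 18723514 and Mir222 at X 18724019 to 18724097 (mm9). Poly-A libraries do not measure mature microRNAs, so the genotype labels could not be checked from these rows. Smarca4 (chromosome 9, 21420613 to 21508674), which encodes the ATPase Brg1 of the SWI/SNF chromatin remodelling complex, had 17.1, 11.7 and 20.1 FPKM in WT naive, LPS and tolerized cells and 18.2, 18.4 and 20.5 FPKM in the KO cells. The Y-linked genes Eif2s3y and Ddx3y were expressed in all libraries, at 29.8 to 45.9 and 23.3 to 35.5 FPKM, while Xist stayed at or below 0.0131 FPKM.

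LPS raised cytokine, chemokine and antiviral transcripts in macrophages of both genotypes. Il6, a pyrogenic cytokine, stood at 1.25 FPKM in WT naive and 4138 FPKM in WT LPS cells and at 7.32 and 5013 FPKM in KO cells, a rise of 10.04 ± 0.56 on the log2 scale (SE, 2 libraries per condition; adjusted p = 0.00034). Cxcl10, an interferon-induced chemokine, rose by 10.15 ± 0.37 (adjusted p = 0.00025) and Tnf by 7.58 ± 0.71 (adjusted p = 0.0006), from 28.7 to 13818 FPKM in WT and from 219.9 to 17407 FPKM in KO cells. Other large increases were those of the antiviral genes Rsad2 (8.90 ± 0.31), Ifit1 (8.36 ± 0.42), Cmpk2 (8.16 ± 0.30) and Oasl1 (7.90 ± 0.42). Il1b, Cxcl1, Il27 and Ch25h, the last an enzyme that hydroxylates cholesterol, rose by 8.10, 8.10, 8.02 and 7.93. Il12b rose by 6.22 ± 0.33 (adjusted p = 0.00034), and Nos2, the inducible nitric oxide synthase, by 5.89 ± 0.72 (adjusted p = 0.0011).

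Among genes lowered by LPS, Cd300lb, an activating receptor of myeloid cells, fell by 5.50 ± 0.41 on the log2 scale, Tmem86a by 5.41 ± 0.32 and Arl11 by 5.02 ± 0.30. Dhrs3, a retinaldehyde reductase, fell by 5.01 ± 0.71 and stood at 294.6 FPKM in WT naive and 55.2 FPKM in KO naive cells. Ypel3, the chemokine receptor gene Cxcr4, the immunoreceptor gene Nfam1 and the amino acid transporter gene Slc43a2 fell by 4.66, 4.52, 4.52 and 4.48. Sesn1 and the peroxisomal transporter gene Abcd2 fell by 4.44 and 4.31.

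Of 21 measured inflammatory cytokines, 20 rose with LPS, also 20 when adjusted over the list alone, and their median lay 6.15 above that of all genes. Of 40 interferon-stimulated genes 38 rose, 39 when adjusted over the list alone, and all 12 interferon-inducible GTPases rose under both adjustments, led by Gbp5 (6.33), Iigp1 (5.39) and Ifi47 (5.15). Of 20 chemokines 14 rose and 1 fell, with the same counts adjusted over the list alone. Of 14 LPS genes listed as SWI/SNF-dependent, 11 rose under both adjustments, among them Cxcl10, Il6, Ifit1 and Ifit3 (7.41). Of 22 negative regulators of Toll-like receptor signalling 14 rose and 3 fell, or 16 and 3 adjusted over the list alone and 18 and 2 after rescaling, with Socs1 (4.63), Il10 (4.28) and Nfkbiz (4.00) leading. Stat2 and Irf9, which transmit interferon signals, rose by 2.89 ± 0.21 and 1.49 ± 0.21 (adjusted p = 0.00042 and 0.0016).

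Lysosomal genes moved the other way. Of 22 measured, 15 fell, or 15 fell and 1 rose adjusted over the list alone and 6 and 1 after rescaling, led by the proton pump subunit gene Atp6v0d2 (-2.95), the lysosomal regulator Tfeb (-2.59) and the cholesterol transporter gene Npc1 (-2.14). Of 13 pan-macrophage markers 5 fell and 1 rose under both adjustments, and 3 and 1 after rescaling. Fcgr3 fell by 2.87 and Csf1r by 2.22, and Cd14, the LPS co-receptor, rose by 1.89. Of 14 B cell markers 8 fell, or 9 fell and 1 rose adjusted over the list alone and 7 and 3 after rescaling, with Cd79b at -2.42 and Fcrla at -2.28. Of 21 SWI/SNF subunit genes 12 fell under both adjustments and 4 after rescaling. Smarca2 fell by 2.66, and Smarca4 differed by -0.25 ± 0.23 (adjusted p = 0.37). The median of these subunits lay 0.02 from that of all genes, of which 5511 of 10139 fell. Relative to all genes the pan-macrophage and B cell marker medians were at -0.08 and -0.28.

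In all, 886 genes rose and 5511 fell among 10139 tested by limma with Benjamini-Hochberg adjustment. The median of all genes was at -0.76 in this contrast, and after the libraries were rescaled to a common median 1769 genes rose and 2948 fell, none changing direction. By size alone, 832 genes were at least 2-fold higher and 4065 lower in WT LPS than in WT naive cells, or 1426 and 2418 after rescaling (all-gene median -0.74 as deposited). In KO cells 703 were higher and 4246 lower, or 1330 and 1866 after rescaling (median -0.83). The WT and KO ratios had a Pearson r of 0.86 across 10443 genes, which are not independent replicates. Both genotypes shared 516 higher genes, against 57 for independent lists, and 3235 lower genes, against 1694. Only 9 genes passed 2-fold in opposite directions.

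**Figure D1:**
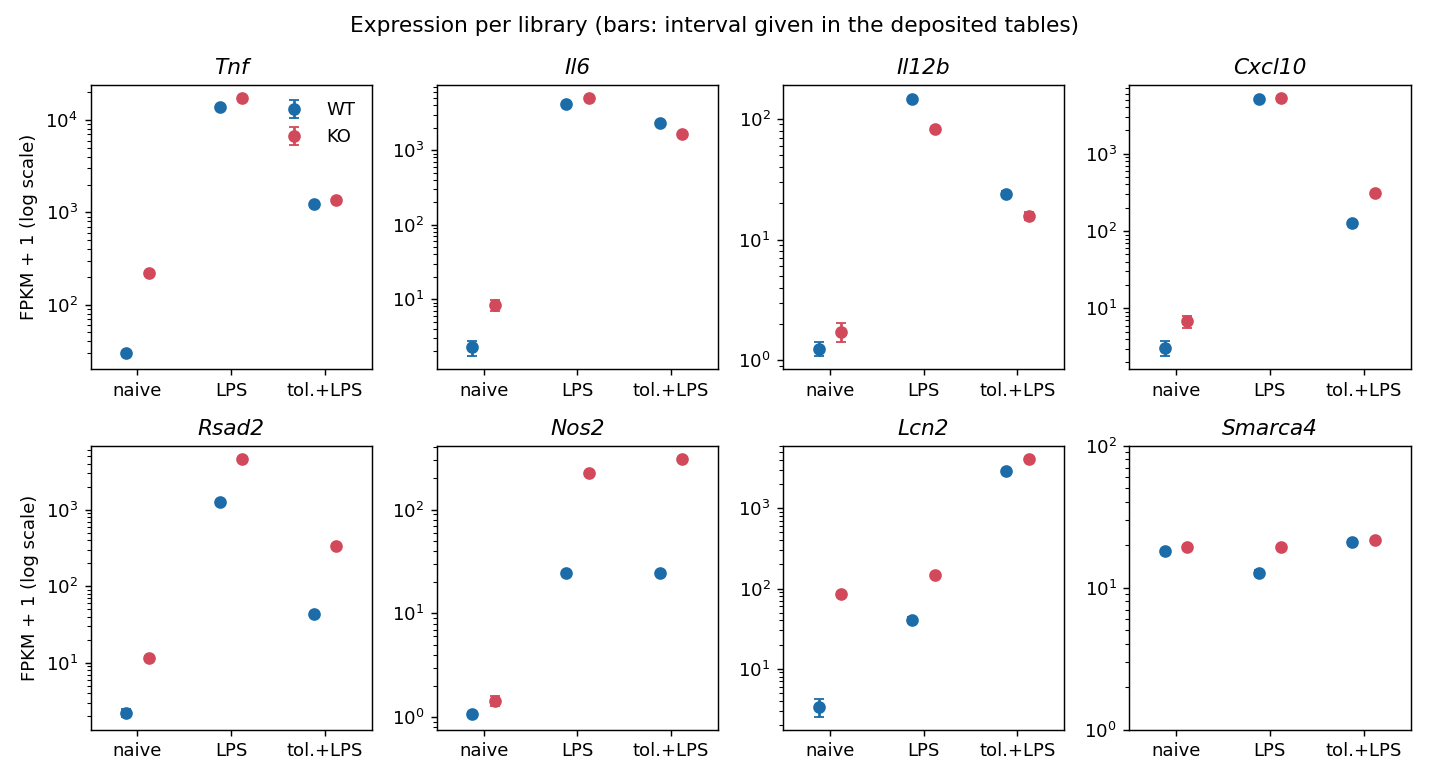
Expression of 8 genes in the 6 libraries, as FPKM + 1 on a log axis, in naive, LPS and tolerized cells of WT (blue) and KO (red) mice, each point being 1 library and each bar the interval in the deposited tables. Tnf was at 13818 and 17407 FPKM with LPS and at 1235 and 1352 FPKM in tolerized cells, whereas Lcn2 reached its highest values, 2862 and 4112 FPKM, in tolerized cells.

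Tolerized cells answered the same LPS dose with far lower antiviral and interferon transcripts. Cmpk2 fell by 4.83 ± 0.30 on the log2 scale relative to LPS alone (adjusted p = 0.0046), Cxcl10 by 4.71 ± 0.37 (adjusted p = 0.0065) and Ifnb1, which encodes interferon beta, 22.7-fold (adjusted p = 0.0081). Tnf fell by 3.58 ± 0.71 (adjusted p = 0.013), from 13818 to 1235 FPKM in WT and from 17407 to 1352 FPKM in KO cells. Tnfsf15, Rsad2 and Ifit2 fell by 4.34, 4.33 and 4.22, and Il15, the zinc finger gene Plagl1 and Fam26f by 3.91, 3.71 and 3.58. Il12b fell 5.65-fold (adjusted p = 0.0079) and Stat2 by 1.33 ± 0.21 (adjusted p = 0.0088). Il6 differed by -1.23 ± 0.56 (adjusted p = 0.12), Nos2 by 0.21 ± 0.72 (adjusted p = 0.83) and Irf9 by -0.54 ± 0.21 (adjusted p = 0.082).

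Other genes were higher in tolerized cells than with LPS alone. Lcn2, a siderophore-binding acute phase protein, rose by 5.47 ± 0.88 (adjusted p = 0.009) and Arg1, the arginine-degrading enzyme, by 5.07 ± 0.27 (adjusted p = 0.0046), from 2.38 to 96.0 FPKM in WT and from 3.47 to 173.7 FPKM in KO cells. The stefin family genes on chromosome 16, 2010005H15Rik, Gm5483 and Stfa3, rose by 6.27 ± 1.05, 4.23 ± 1.11 and 3.83 ± 0.46, and Saa1 by 3.60 ± 0.44. These belong to families of similar genes whose reads can be shared, so the value of each member is uncertain. Gp6, Cyp1b1, Gpr35 and A830007P12Rik rose by 3.68, 3.34, 3.23 and 3.22.

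Of 21 inflammatory cytokines 13 fell and 2 rose, with the same counts adjusted over the list alone and 13 and 1 after rescaling. Of 40 interferon-stimulated genes 25 fell, 29 adjusted over the list alone and 31 after rescaling, with Mx1 at -3.55 beside Cmpk2, Rsad2 and Ifit2. Of 12 interferon-inducible GTPases 10 fell under both adjustments, among them Iigp1 (-3.08), Ifi47 (-2.81) and Gbp5 (-2.72). Of 20 chemokines 2 fell and 1 rose, or 2 and 0 adjusted over the list alone and 4 and 0 after rescaling, and their median lay at -1.30 relative to all genes. Cxcl10 fell, Cxcl5 was at 2.06 (adjusted p = 0.047 as deposited, not passing over the list alone or after rescaling), and Ccl4 differed by -2.52 (adjusted p = 0.084). Of the 14 SWI/SNF-dependent LPS genes 6 fell and 2 rose under both adjustments, and 6 and 1 after rescaling. Of 14 genes listed as escaping silencing in tolerance 1 rose, Lcn2, also 1 adjusted over the list alone, and 1 rose and 1 fell after rescaling. Saa3 and Hp, acute phase genes, differed by 1.48 (adjusted p = 0.31) and 1.37 (adjusted p = 0.12).

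Of 19 glycolysis and hypoxia genes 10 rose and 2 fell, or 11 and 2 adjusted over the list alone and 5 and 2 after rescaling. Bnip3 rose by 3.15, the lactate transporter gene Slc16a3 by 2.92 and the hypoxia sensor gene Egln3 by 2.86. Of 15 cell cycle genes 10 rose and 2 fell, or 10 and 3 adjusted over the list alone and 7 and 3 after rescaling, with Top2a at 1.99 and Rrm2 at 1.84. B cell markers moved with them: 8 of 14 rose, 10 adjusted over the list alone and 3 after rescaling, with Cd22 at 1.63 and Fcrla at 1.58. So did T and NK cell markers, of which 5 of 6 rose, 6 adjusted over the list alone and 0 after rescaling. Inpp5d, a phosphatase that limits Toll-like receptor signalling, rose by 2.98.

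Across all genes 3733 rose and 438 fell in the limma fit, around an all-gene median of 0.51, and 1156 rose and 746 fell after rescaling. These counts rested on single libraries: without the WT LPS library 1165 rose and 212 fell, without KO LPS 197 and 70, without WT tolerized 1997 and 270, and without KO tolerized 1636 and 318. By size, 2001 genes were at least 2-fold higher and 437 lower in WT (median 0.47; 903 and 815 after rescaling) and 2307 and 414 in KO cells (median 0.56; 920 and 862 after rescaling). The WT and KO ratios had an r of 0.74 across 9863 genes, with 1287 genes higher in both against 478 for independent lists and 249 lower in both against 19.

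Against naive cells, tolerized cells kept high cytokine expression. U90926, a transcript on chromosome 5, rose by 9.10 ± 0.24 on the log2 scale (adjusted p = 0.00014), from 0.461 to 864.8 FPKM in WT and from 1.11 to 1075 FPKM in KO cells. Il6 rose by 8.81 ± 0.56 (adjusted p = 0.0016), Lcn2 by 7.66 ± 0.88 (adjusted p = 0.004), Il1b by 7.53 ± 1.15 (adjusted p = 0.0076) and Ptgs2, the inducible prostaglandin synthase, by 7.45 ± 0.86 (adjusted p = 0.004). Cxcl1, Csf3, Ch25h, Il1a and Cxcl3 rose by 6.69, 6.69, 6.61, 6.55 and 6.54. Nos2 rose by 6.11 ± 0.72, Tnf by 4.00 ± 0.71 and Il12b by 3.73 ± 0.33 (adjusted p = 0.0041, 0.011 and 0.0023), and Stat2 and Irf9 by 1.55 and 0.95 (adjusted p = 0.0056 and 0.021). Atp6v0d2 fell by 5.52 ± 0.26 (adjusted p = 0.0016), the lipid-sensing receptor gene Trem2 by 4.29 ± 0.39 (adjusted p = 0.0024), Mtus1 by 4.15 and Ltc4s, the leukotriene C4 synthase, by 4.11. Abcd2, the selenoprotein gene Sepp1, the complement receptor gene Vsig4 and 2400009B08Rik fell by 4.07, 3.87, 3.83 and 3.83, and Ldhb by 3.82. The averages for Sepp1 and Vsig4 came mostly from WT, at -5.30 and -6.32 there against -2.43 and -1.34 in KO. Vsig4 stood at only 1.87 FPKM in KO naive cells.

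Of 40 interferon-stimulated genes 37 were raised over naive, 39 adjusted over the list alone, and of 21 inflammatory cytokines 17 under both adjustments. Of 20 chemokines 13 rose and 1 fell, or 15 and 2 adjusted over the list alone. Of 13 pan-macrophage markers 6 fell and 2 rose, or 6 and 3 adjusted over the list alone, including Lyz1 (-2.70), while the Fc receptor gene Fcgr1 rose by 3.04. Of 16 markers of large peritoneal macrophages 6 fell and 2 rose, or 8 and 2 adjusted over the list alone and 4 and 2 after rescaling, with the transcription factor gene Gata6 at -2.33 and Alox15 at -3.16. Of 22 lysosomal genes 10 fell, or 15 fell and 1 rose adjusted over the list alone, led by Atp6v0d2, with Lipa falling by 2.16 and Ctsd by 1.99. In total 751 genes rose and 2000 fell in the limma fit, around an all-gene median of -0.22, or 892 and 1305 after rescaling. Without the WT naive library 485 rose and 1136 fell, without WT tolerized 504 and 1004, and without KO tolerized 585 and 1300. By size, 822 and 1733 genes were higher and lower in WT (median -0.24) and 644 and 1349 in KO cells (median -0.22), where rescaling gave 796 and 932. The WT and KO ratios had an r of 0.78, with 469 genes higher in both against 52 for independent lists and 925 lower in both against 227.

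Of 519 genes at least 2-fold higher with LPS in both genotypes, 187 were at least 2-fold lower in tolerized than in LPS cells of both genotypes. After rescaling 347 of 944 induced genes were. Independent lists of the 295 induced and tolerized genes of WT and the 302 of KO, among 10579 genes, would share 8.4. That count also covers the shared induction, so it is no reference for the 519. In each genotype induction and tolerization use the same LPS library, so part of the 187 may come from that shared library. A further 190 stayed within 2-fold in both, 128 passed 2-fold in 1 genotype only or on opposite sides, and 14 were at least 2-fold higher again, 7 of them also after rescaling. Those 14 were Csf3, Cxcl5, Gja1, H2-T22, Il1f6, Mmp13, Ntng2, Pdpn, Serpinb2, Slamf1, Slc1a2, Tarm1, U90926 and Zfp811, named after their values were seen, and the 7 were Gja1, Il1f6, Mmp13, Pdpn, Slamf1, U90926 and Zfp811. Mmp13, a collagenase, stood at 126.1 and 648.9 FPKM in WT LPS and tolerized cells, and Csf3, the neutrophil growth factor, at 36.2 and 400.5 FPKM. In KO cells Mmp13 stood at 126.7 and 584.3 FPKM and Csf3 at 136.3 and 373.7 FPKM, for Csf3 below 2-fold after rescaling (0.93).

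**Figure D2:**
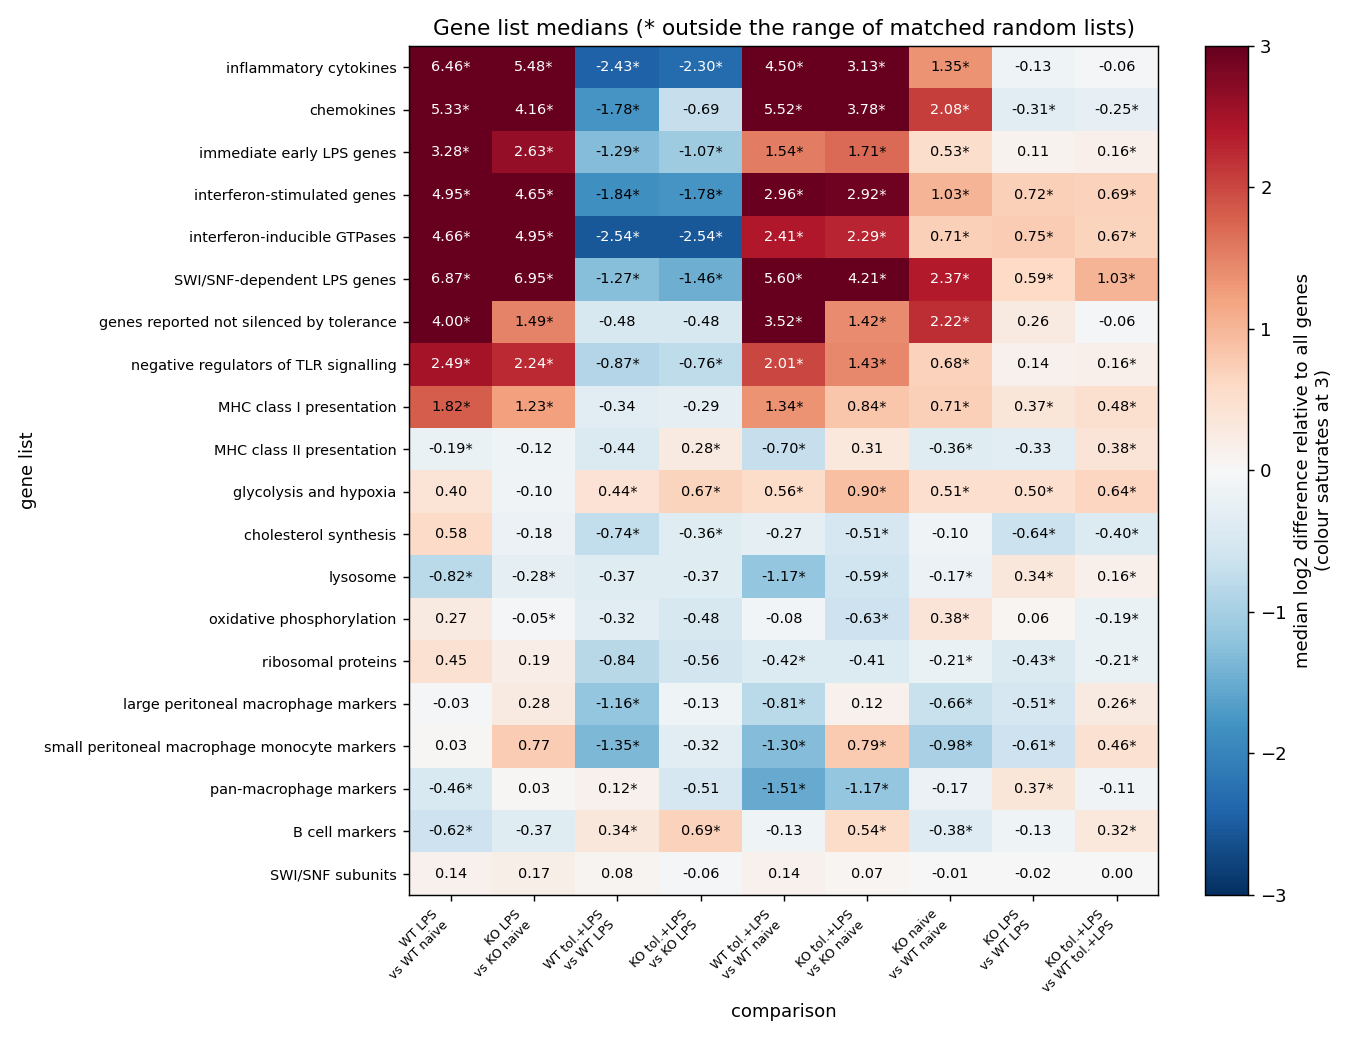
Median log2 difference of 20 gene lists relative to the median of all genes (colour, saturating at 3, and printed value) in the 9 comparisons of single libraries; a star marks a median outside the central range of 10000 expression-matched random lists. Interferon-stimulated genes lay at 4.95 and 4.65 with LPS, at -1.84 and -1.78 after tolerization, and above 0 in all 3 comparisons of KO with WT.

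Naive KO macrophages held more LPS-response transcripts than naive WT macrophages. Il1b stood at 175.2 FPKM in KO and 10.2 FPKM in WT naive cells, Cxcl3 at 207.4 and 7.82 FPKM, Ccl5 at 484.2 and 54.0 FPKM, Tnf at 219.9 and 28.7 FPKM and Lcn2 at 84.7 and 2.37 FPKM. Relative to all genes, the median was 2.08 higher for chemokines, 1.35 for inflammatory cytokines, 2.37 for SWI/SNF-dependent LPS genes and 2.22 for genes listed as escaping tolerance, each above the range of matched random lists. Among the last list, the formyl peptide receptor gene Fpr2 stood at 573.8 against 35.7 FPKM, and the lectin gene Clec4e also belonged to its 4 largest differences, at 3.43. Lists of peritoneal macrophage and monocyte markers lay lower in the KO naive library. The large peritoneal macrophage list was at -0.66 and the small peritoneal macrophage and monocyte list at -0.98, both below the random range. Vsig4 had 1.87 against 158.5 FPKM, the coagulation factor gene F5 3.39 against 47.4 FPKM and the chemokine receptor gene Cx3cr1 1.31 against 12.2 FPKM. Not every monocyte gene was lower: Ly6c2, named after its values were seen, had 33.8 FPKM in KO and 3.95 FPKM in WT naive cells. It was at least 2-fold higher in KO in all 3 conditions. The pan-macrophage median, at -0.17, lay within that range, and the B cell marker median was at -0.38, below it.

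With LPS, the cytokine list lay at -0.13, within the random range, and the chemokine list at -0.31, below it. Ifnb1 stood at 134.0 FPKM in KO and 13.5 FPKM in WT cells, Tnfsf15 at 310.0 and 67.1 FPKM, and Csf2, a myeloid growth factor, at 48.6 and 388.4 FPKM. Cholesterol synthesis genes lay at -0.64 with LPS and -0.40 in tolerized cells, both below the random range, with Fdft1 at 3.65 against 11.9 FPKM and Idi1 at 15.3 against 42.1 FPKM with LPS. Glycolysis and hypoxia genes lay above it in naive, LPS and tolerized cells, at 0.51, 0.50 and 0.64. In tolerized cells Bnip3 had 59.5 FPKM in KO and 15.7 FPKM in WT cells, and Nos2 304.4 and 23.3 FPKM. The large and small peritoneal macrophage lists, at -0.51 and -0.61 with LPS, were at 0.26 and 0.46 in tolerized cells.

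Interferon-stimulated genes were higher in the KO library of every condition, with medians of 1.03, 0.72 and 0.69 relative to all genes in naive, LPS and tolerized cells, all above the random range. Rsad2 had 10.6, 4650 and 331.5 FPKM in KO and 1.23, 1273 and 43.1 FPKM in WT cells. Ifit2 had 4.03, 1025 and 67.2 FPKM against 0.849, 181.6 and 6.94 FPKM, and Irf7, a transcription factor of the interferon response, 110.5 against 7.45 FPKM in naive cells. Of the 40 members, 31 were higher in KO in all 3 conditions. Interferon-inducible GTPases lay at 0.71, 0.75 and 0.67, with Iigp1 at 323.1 against 54.7 FPKM with LPS. B cell markers, at -0.38, -0.13 and 0.32 in the same comparisons, crossed from below to above the random range.

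**Figure D3:**
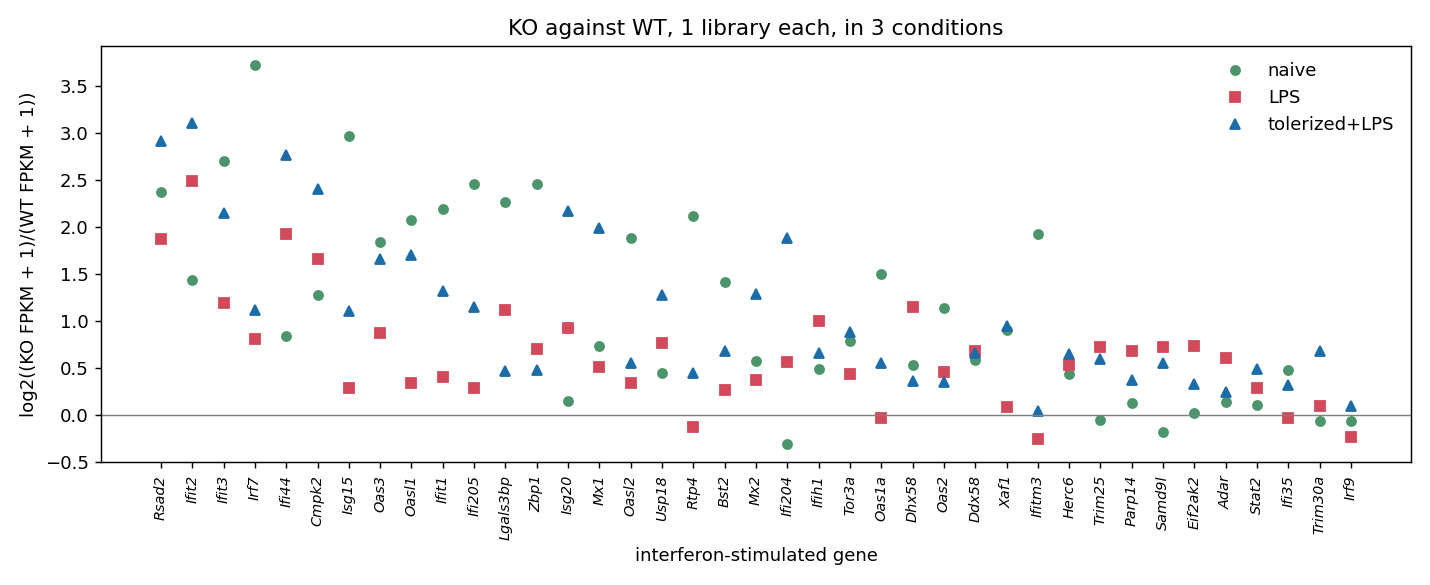
Log2 ratio of KO to WT (FPKM + 1) of 39 of the 40 interferon-stimulated genes in naive (circles), LPS (squares) and tolerized (triangles) cells, each point comparing 1 library with 1 library, ordered by the mean of the 3. Of all 40 members 31 had a ratio above 0 in all 3 conditions, and 0 had a ratio below it in all 3.

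When the genotypes were compared across the 3 conditions (limma, 3 libraries each), 0 of 10139 genes passed Benjamini-Hochberg adjustment, before and after rescaling. An unadjusted p under 0.05 was reached by 707 genes, and the smallest adjusted p was 0.11. Without the WT tolerized library 152 genes rose and 83 fell in KO, and without the KO tolerized library 155 and 82. Both of these fits estimate the genotype difference from the naive and LPS libraries alone, so they are a single check. The count of 0 thus depended on the tolerized pair. The largest mean differences with a common direction were Ly6i (4.21 ± 0.87, adjusted p = 0.38), the cystatin gene Cst7 (3.62 ± 0.48, 0.16), Susd2 (2.69 ± 0.60, 0.38), the costimulatory ligand gene Tnfsf4 (2.66 ± 0.33, 0.16) and 9030425E11Rik (2.45 ± 0.56, 0.38). Nos2 was at 2.43 ± 0.59, Rsad2 at 2.39 ± 0.25, Lcn2 and Ifit2 both at 2.35, and the acute phase gene Orm1 at 2.34 (adjusted p = 0.42, 0.13, 0.54, 0.16 and 0.26). Lower in KO were Vsig4 (-3.91 ± 0.90, 0.38), the ribonuclease gene Ear2 (-3.51 ± 0.82, 0.4), the lectin gene Cd209a (-2.95 ± 0.87, 0.53), Apoc4 (-2.67 ± 0.80, 0.53) and the protease inhibitor gene Ctla2a (5.64-fold, adjusted p = 0.11). F5, F13a1, Apoc1 and the globin gene Hbb-b2 were at -2.26, -2.19, -2.14 and -2.08, and Sepp1 was 3.99-fold lower. Ly6i, Ear2, Orm1 and Hbb-b2 have near-identical relatives and are uncertain.

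Smarca4 differed by 0.24 ± 0.19 between genotypes (adjusted p = 0.83), Tnf by 1.12 ± 0.58 (0.79), Il6 by 0.55 ± 0.46 (0.84), Il12b by -0.31 ± 0.27 (0.84), Stat2 by 0.30 ± 0.17 (0.8) and Irf9 by -0.06 ± 0.17 (0.94). Adjusted over the list alone, 26 of 40 interferon-stimulated genes rose in KO, 6 of 12 interferon-inducible GTPases, 6 of 14 SWI/SNF-dependent LPS genes and 3 of 19 glycolysis and hypoxia genes, against 0 of each over all genes. The SWI/SNF-dependent list holds antiviral and interferon-induced genes such as Ifit1 and Cxcl10, so its count is not separate from the interferon result. Of 18 cholesterol synthesis genes 7 fell adjusted over the list alone, and the largest differences were Idi1 at -0.90 ± 0.22 and Fdft1 at -0.82 ± 0.25. Of 16 large peritoneal macrophage markers 5 fell and 1 rose, and of 10 small peritoneal macrophage and monocyte markers 4 fell and 1 rose, adjusted over the list alone. Of 3 eosinophil markers 2 fell adjusted over the list alone, with a median of -0.96 relative to all genes. Between conditions, the KO to WT ratios had an r across 10579 genes of 0.30 for naive and LPS, 0.00 for naive and tolerized, and 0.30 for LPS and tolerized cells. On ranks (Spearman) these were 0.09, -0.12 and 0.26.

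By size, 404 genes were at least 2-fold higher and 319 lower in KO than WT naive cells, 362 and 264 with LPS, and 175 and 75 in tolerized cells. Rescaling gave 518 and 219 with LPS, where the all-gene median was at -0.13. In all 3 conditions 23 genes were higher, against 0.25 for independent lists, and 7 lower, against 0.06. The higher ones included Tnfsf4, Rsad2, Cmpk2, Ifit2, Ifit3, Cst7, Orm1, Siglec1 and Il18bp, and the lower ones were Fn1, F5, Igfbp4, Cxcl14, Ctla2a, Pros1 and Hbb-b2, named after their values were seen. Fn1, which encodes fibronectin, stood at 803.7, 676.4 and 175.4 FPKM in WT naive, LPS and tolerized cells.

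The loss of expression on tolerization was of similar median size in both genotypes. Over 270 genes induced and tolerized on the mean of WT and KO, the KO change from LPS to tolerized minus the WT change had a median of 0.09, at percentile 13.8 of matched random lists, and the all-gene median was also 0.09. After rescaling the median was -0.09, so its direction depended on the scaling. No p-value can be had for this difference, because it leaves no residual degrees of freedom. Of the 270, 50 were at least 2-fold higher and 7 lower in KO than WT tolerized cells, and the median KO to WT difference was 0.38 there, 0.36 with LPS and 0.18 in naive cells. Among genes of at least 10 FPKM, the change was higher in KO than WT for Fabp7, a fatty acid-binding protein with 892.4 and 112.8 FPKM in WT LPS and tolerized cells and 43.5 and 138.3 FPKM in KO cells. Next came Mmd, Selp, Ccl12, Emp1 and Pdgfb. Ear2, Vsig4 and Cd209a also ranked there, but at 1.24 FPKM or less in KO LPS and tolerized cells they had no room to fall in KO. Ccl12, a monocyte chemoattractant, had 12.4 and 2.90 FPKM in WT and 20.6 and 72.6 FPKM in KO cells. It was lower in KO for Gm5483, Emr4, Ly6i, Inhba, 1100001G20Rik, Mmp9, 2010005H15Rik, Itgb8, Mertk and Susd2. Mertk, a receptor for apoptotic cells, had 8.37 and 13.1 FPKM in WT and 114.2 and 22.8 FPKM in KO cells.

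Genes with a match to the miR-221/222 seed in the 3′ UTR of the longest coding transcript were compared between genotypes, since loss of a microRNA is known to raise its direct targets. The sites searched were ATGTAGC and ATGTAGCA, and a UTR was found for 96.7% to 97.3% of the genes compared. The median KO to WT difference of genes with a site exceeded that of lists matched on expression and UTR length by 0.001 in naive (1086 genes), 0.011 in LPS (896) and 0.012 in tolerized cells (1034). These lay at percentiles 52.0, 70.4 and 89.3, inside the range of random lists. Among shuffled seeds they lay at 62.4, 78.5 and 85.1. With ATGTAGCA alone, the values were -0.027, 0.054 and 0.031, at percentiles 10.1, 94.1 and 97.7, the last above the range. The 1262-base UTR of Smarca4 held 0 sites, Kit 2, Ets1 2 and Cdkn1b 1.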

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

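The tests of mixed RNA, of macrophage and B cell shares, of scaling, of the choice of tolerized genes and of all genes over other splits were chosen only after the result was seen, the gene set of the mixing test was narrowed after a first run, and its repeat on fixed lists was added last. The differences given here between conditions or genotypes were not tested, since single libraries leave no test of an interaction.

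Several lists lay outside the range of random lists in opposite directions under different conditions or genotypes. Between KO and WT, relative to all genes, chemokines were at 2.08 in naive but -0.31 in LPS and -0.25 in tolerized cells, and oxidative stress and metal response genes at 0.81 in naive and -0.34 in LPS cells. Lysosomal genes were at -0.17 in naive, 0.34 in LPS and 0.16 in tolerized cells, and respiratory chain genes at 0.38 in naive and -0.19 in tolerized cells. Reported miR-221/222 targets were at -0.27 in naive and 0.20 in tolerized cells, MHC class II genes at -0.36 and 0.38, and B cell markers at -0.38 and 0.32. Large peritoneal macrophage markers were at -0.66, -0.51 and 0.26 in naive, LPS and tolerized cells, and small peritoneal macrophage and monocyte markers at -0.98, -0.61 and 0.46. The last list was at -1.30 for tolerized against naive WT cells and at 0.79 for KO cells.

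Single genes showed the same kind of opposite movement. Between KO and WT, 2010005H15Rik was at 3.18, 1.75 and -1.83 in naive, LPS and tolerized cells, Gm5483 at 1.60, 1.39 and -3.25, and Cxcl3 at 4.56, -1.28 and -1.47. Selp was at -1.77, -1.32 and 2.27, Emp1 at -1.42, -1.52 and 1.74, and Emr4 at 1.90, 2.53 and -1.81. From LPS to tolerized cells, Fabp7 was at -2.97 in WT and 1.65 in KO, Ccl12 at -1.78 and 1.77, and 1100001G20Rik at 2.64 and -1.23. From naive to tolerized cells, Apoc1 was at -1.70 in WT and 1.02 in KO, Emp1 at -1.84 and 1.32, and 1100001G20Rik at 4.04 and -1.60. From naive to LPS cells, Mmd was at 1.99 in WT and -1.33 in KO, and Mertk at -2.54 and 1.71. Among the small RNA rows left out of the comparisons, Mir703 was listed at 12205 FPKM in WT LPS and 6241 FPKM in WT naive cells, with intervals of 8347 to 16062 and 3638 to 8843 that overlap.

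LPS-response genes were higher in the KO naive library than in WT naive: of 404 genes at least 2-fold higher there, 298 were also induced by LPS or tolerization in WT (a count the shared WT naive library can raise), and of 83 members of the lists of cytokines, chemokines, interferon-stimulated, SWI/SNF-dependent and tolerance-escaping genes, fixed before the data were examined, 53 were higher and 0 lower. Each abundant LPS gene sets an upper bound on the share of KO LPS RNA in KO naive cells, and the median of the 5 lowest bounds was 0.246%. Taking out that share left 96.3% of the 298 and 88.7% of the 53 at least 2-fold higher. For KO tolerized RNA the share found in the same way was 2.10%, which left 86.6% and 73.6%. These values argue against mixing as the whole cause. The pan-macrophage median of -0.17 compares 1 library with 1 library, so it cannot decide on a higher share of macrophages. With LPS itself 5 of the 13 markers fell and 1 rose, while 5511 of all 10139 genes fell. Relative to all genes their median was at -0.08 with LPS. The B cell marker median of -0.38 cannot decide on it either, for the same reason. Of those 14 markers 8 fell with LPS, with a median of -0.28 relative to all genes. Earlier LPS exposure of the KO naive cells may account for the higher LPS-response genes and cannot be told apart from a genotype effect. The KO to WT ratios had a Pearson r of 0.11 with the WT change from LPS to tolerized cells, just above the bound of 0.1 set against earlier exposure. The Spearman rho was 0.02. Against counts for independent lists, 143 genes (81.3) were higher and 60 (13.5) lower in both. Another 29 (62.5) were lower in KO naive and higher after WT tolerization, and 55 (17.5) were higher in KO naive and lower after it. Both libraries of that WT change received LPS for 4 h and the KO naive cells did not, so these values cannot decide on earlier exposure. Tnf, for example, was at 2.89 between KO and WT naive cells and at -3.48 in that WT change. A genotype effect, a different state of the cells before culture, a different share of macrophages and a difference between single libraries stay open.

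Interferon-stimulated genes were higher in KO than WT in all 3 conditions. Scaling does not account for it, since the median of the mean ratio was 0.78 after rescaling and 0.73 as deposited. B cell markers moved from below the random range in naive to above it in tolerized cells, by 0.70, so they were not shifted the same way in every condition. A B cell share that differs from library to library cannot be decided on, since each group is 1 library. Of the 10 splits of the 6 libraries, 1 called as many list members as the real split, itself, with 26 members against 8 in the highest other. The splits with 8 rested on the naive KO and WT libraries alone, since the fit also holds condition, so they carry the genotype difference. Besides, 10 splits are too few for a share under 0.05. A genotype effect may account for the pattern, but with 1 library per group it cannot be told apart from differences between animals or cultures.

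Genes tolerized in WT showed less tolerization in KO, with a median difference of 0.42 at percentile 100. Genes chosen in KO gave -0.22, at percentile 0, and genes chosen on the mean of both gave 0.09, within the range of random lists. This is consistent with the choice of genes on the WT libraries as the source of the 0.42. A smaller genotype effect on tolerization stays open, as no test of it can be had from these libraries.

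The tests over other splits of the 6 libraries can give no share under 0.05 with 10 splits. Splits with both libraries of a condition on the same side rest on the KO and WT libraries of a single condition. They still carry the genotype difference, so their counts are no measure of chance. All 10 splits called as many genes as the real one, 0, with 0 in the highest other. Over the list alone, 6 interferon-inducible GTPases were called, with 0 in the highest other split and 1 split as large, the real one. SWI/SNF-dependent LPS genes had 6, with 8 in the highest other and 3 splits as large. The real and highest other counts were 7 and 0 for cholesterol synthesis, 3 and 1 for glycolysis and hypoxia, 6 and 2 for large and 5 and 1 for small peritoneal macrophage markers, with 1 split as large in each.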

How the results depend on the processing

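The small RNA rows and repeated symbols were kept as a test chosen only after the data were seen. Of 218 values of results that answer a comparison under an alternative, 181 stayed on their side of the threshold or within 1.5 times, 32 moved beyond that and 5 passed a threshold, with 0 called in both directions. Of 824 list medians 786 kept their call, 15 gained one and 23 lost one, and of 3692 values of named genes 3369 kept theirs, 205 gained one and 118 lost one. With libraries rescaled, genes higher and lower by size were 1426 and 2418 (WT LPS against naive), 1330 and 1866 (KO), 903 and 815 (WT tolerized against LPS) and 920 and 862 (KO). In the limma fit they were 1769 and 2948 for LPS against naive, 1156 and 746 for tolerized against LPS, and 1305 lower for tolerized against naive. Genes tolerized in both genotypes became 347 and the median difference of tolerization -0.09, its sign turned from 0.09. Rescaling lowers the LPS shift of the all-gene median by construction. That difference was 0.07 with a pseudocount of 0.1, and 0.42 and -0.22 for genes tolerized in WT or KO alone. The r of WT and KO responses was 0.87 for LPS against naive and 0.79 for tolerized against naive with a filter of 5 FPKM, and the excess of seed genes in tolerized cells was 0.031 with ATGTAGCA alone, while the naive excess of 0.001, within the random range, turned to -0.027 there and to -0.004 with the 5 FPKM filter. The cause of these was not tested.

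Leaving out each library in turn, which can leave a condition with 1 library assumed to vary like the others, gave 197 to 4133 higher and 70 to 566 lower genes for tolerized against LPS. It gave 485 to 720 higher and 1004 to 1709 lower for tolerized against naive, and 0 to 155 higher and 0 to 83 lower for KO against WT. The fewest for tolerized against LPS came without KO LPS, and for KO against WT genes were called only without a tolerized library, of WT (152 and 83) or KO (155 and 82). For the genotypes, leaving out either tolerized library is a single check, as both fits rest on the naive and LPS libraries alone. With the small RNA rows kept, 1 gene was lower in KO, Mir7-1, listed at 327.3, 359.0 and 280.3 FPKM in WT and at 0 in KO, with WT intervals starting at 0, so depth cannot show a difference. No paired analysis was possible because each group holds 1 library, beyond the limma fit itself, which compares the genotypes within conditions. Below 5 FPKM the intervals, of 13.7% to 16.1% on either side, limit what differences can be seen.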

Other observations

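The alternative with small RNA rows and the splits of all genes were tests chosen only after the result was seen, and the seed site test reported here was planned. Some antigen presentation and stress genes also moved with LPS, where 886 of all 10139 genes rose and 5511 fell as deposited. Of 18 MHC class I genes 9 rose with LPS, 8 adjusted over the list alone and 12 after rescaling, with the peptide transporter gene Tap1 at 2.76 and the activator gene Nlrc5 at 2.72, while H2-Q7 rose by 1.97 from LPS to tolerized cells. Of 11 MHC class II genes 5 fell with LPS under both adjustments and 3 after rescaling, with H2-Ob at -1.85 and the master regulator Ciita at -1.75. From LPS to tolerized cells Ciita rose by 1.66, and 4 of the 11 rose under both adjustments and 1 after rescaling, while 3733 of all 10139 genes rose. Relative to all genes the class II median was at -0.06 and -0.03 in these contrasts, so the list hardly moved apart from all genes. B cell markers moved the same way as class II genes, 8 of 14 falling with LPS and 8 rising from LPS to tolerized cells. A change in B cell share was thus not separated from one in macrophages. Of 13 costimulation and checkpoint genes 8 rose and 2 fell with LPS, or 9 and 2 adjusted over the list alone and 10 and 2 after rescaling, with Cd40 at 4.79 and Tnfsf9 at 4.72. Of 17 heat shock and unfolded protein genes 6 rose, 4 adjusted over the list alone and 11 after rescaling, led by Hspa1a (2.77) and Hspa1b (2.68), near-identical copies whose reads can be shared.

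Of 20 genes on the histone modifier list 3 rose and 8 fell with LPS under both adjustments, and 6 and 5 after rescaling. The histone demethylase gene Kdm6b rose by 3.08, and Dnmt1, a DNA methyltransferase gene that the list also holds, fell by 2.88. From LPS to tolerized cells 10 rose and 1 fell, or 11 and 2 adjusted over the list alone and 2 and 2 after rescaling, with Dnmt1 at 2.01 and Kdm5b at 1.87. Of 11 liver X receptor targets 6 fell and 1 rose with LPS under both adjustments, or 4 and 1 after rescaling. With LPS 5511 of all 10139 genes fell, and relative to all genes the histone modifier median was at 0.20 and that of these targets at -0.22. Scd2 fell by 3.42 and the cholesterol exporter genes Abca1 and Abcg1 by 2.87 and 2.53, and Abca1 rose by 2.38 from LPS to tolerized cells. Hdc, which makes histamine, rose by 4.27 with LPS, and Ccnd2, a G1 cyclin, by 4.64.

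A rise of direct miR-221/222 targets in KO was a hypothesis of the design, predicting medians above the range of matched lists in all 3 conditions. The highest of the 3 percentiles was 89.3, within the range, where a simulated rise of 0.2 reached percentile 100 in each condition. Smaller rises were not simulated and stay open. With ATGTAGCA sites alone the tolerized excess was 0.031, at percentile 97.7, but the naive value was -0.027, at percentile 10.1, and the LPS value 0.054, at 94.1, so no common shift was seen.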
